A study of Solanum lycopersicum with 36 samples.

How the data were processed

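Nuclear RNA was measured in the fruit wall (pericarp) of tomato, Solanum lycopersicum, of the cherry type line WVA106. Fruits of 3 ages were used, counted in days after the flower opened (DPA, for days post-anthesis): 6, 9 and 12. Per the labels' protocols, nuclei were released from the pericarp of 20 fruits at 6 DPA and of 10 fruits at the later stages, stained for DNA and sorted by DNA content. The unit C is the DNA amount of an unreplicated haploid genome, so that 4C nuclei hold 2 times the DNA of 2C nuclei. Each sample was RNA from 100000 sorted nuclei, and per the same protocols the same amount of ERCC RNA, a set of synthetic transcripts, was added to each sample before RNA extraction. Libraries were stranded and paired-end, and were treated with a duplex-specific nuclease, an enzyme that removes the cDNA of very abundant transcripts.

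The authors deposited 1 table of raw counts, whole numbers that were not normalized, with 36573 genes, 92 ERCC species and 1 column for each of the 36 libraries. All 36 columns were used. Per the submitters' processing notes, the tools were FastQC, cutadapt, STAR, featureCounts, Subread and DESeq2. Versions, settings, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Reads shared between near-identical genes, or between overlapping genes, can therefore have been counted in ways that cannot be traced, and single genes of such families are uncertain. None of the 36573 identifiers matched the reference table of gene names (assembly SLM_r2.1, 0 identifiers matched), and the count table does not pair identifiers with names. The gene lists, the panel of well-known fruit genes and the rule for named genes, all fixed before the data were examined, need names or product descriptions and were not run. At most 2 identifiers that rose and 2 that fell are printed instead. They are the ones with the largest mean slope either way among genes called at all 3 stages with a mean of at least 10 CPM (counts scaled to a common library size) at each stage, a rule set after the data were examined.

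Gene counts per library ran from 137649 to 3539295, with a median of 912926, and ERCC counts from 142 to 13452. The counting error of the ERCC total was 0.862 to 8.39% of its value. A gene with 0 counts in a library could have been present at up to 3 counts, which is 0.848 CPM in the deepest library and 21.8 CPM in the shallowest. Intervals and floors cover counting error only. No pair of replicate libraries agreed within sampling noise, with a chi-square per degree of freedom of 1.62 to 4.60 over 36 pairs, so each library was counted as 1 replicate.

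Samples were grouped by stage and DNA content from their titles, giving 12 groups of 3 biological replicates. Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, filterByExpr, estimateDisp, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene past that threshold is said to have been called. For each stage, a slope on log2 DNA content was fitted over the 12 libraries, so that its coefficient is a log2 change per doubling of DNA. The highest class was compared with the lowest in a model with 1 mean per class. Stages were compared over the 4C, 8C and 16C classes, which were sorted at every stage, with equal weight for each class. The difference between the slopes at 12 and 6 DPA was tested as an interaction over the same classes. With TMM scaling these tests compare shares of the nuclear RNA. For changes per nucleus, the slopes were fitted again with the ERCC total of each library in place of its library size.

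The ratio of all gene counts to all ERCC counts was used as a measure of RNA per nucleus. Its slope on log2 DNA content was tested with a two-sided permutation test with 100000 permutations, whose smallest possible p is 1e-05. Stages were compared on the same ratio with a two-sided exact permutation test within classes. Principal components were computed from log2 CPM with a prior count of 2 over 16481 genes.

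The test scripts were tested on simulated counts with known slopes, drawn from the real means and depths with the same dispersion of 0.05 for every gene. No other difference between groups was simulated. Shares recovered are of the changed genes that passed the filter, which at 6 DPA were 89 with a slope of 1 and 76 with a slope of 0.5. Of simulated genes with a slope of 1, 100% were recovered at 6 DPA over 13206 genes tested, 98.8% at 9 DPA over 11549 and 98.9% at 12 DPA over 14568. For a slope of 0.5, the shares were 56.6, 66.7 and 79.3%. Of the genes called on the simulated slopes, 4.35, 5.38 and 7.02% had not been changed, and between the simulated end classes 9.56, 4.13 and 6.63%, so the threshold of 0.05 was exceeded in part. For the difference between slopes, 52.7% were recovered at a size of 1 and 8.14% at a size of 0.5 over 14915 genes, with 5.17% false calls. Between 12 and 6 DPA, 80.0% of differences of 1 and 15.8% of differences of 0.5 were recovered over 15144 genes, with 3.61% false calls.

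The alternatives fixed before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 1 CPM, the replicate number as a block, all 36 libraries in 1 fit, removal of genes over 1% of any library, an adjusted p under 0.01, ERCC factors by median of ratios, and leaving out each library. Added after the data were seen were thinning of a stage's libraries to equal depth in 5 draws and leaving out 3 shallow libraries. These were replicate 3 of 4C and of 8C at 9 DPA, and replicate 2 of 4C at 6 DPA. Tests of neighbouring classes, also with library sizes alone, and tests of curvature over the 4 classes were added then too.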

Results

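Pericarp nuclei were sorted by DNA content at 3 stages of early tomato fruit growth, to ask how the nuclear transcriptome differs between these classes. DNA content rises with rounds of DNA replication without division (endoreduplication). A nucleus that has replicated its DNA before a division also holds more, and DNA content alone does not tell them apart. Nuclei of 2C, 4C, 8C and 16C were collected at 6 DPA, and nuclei of 4C, 8C, 16C and 32C at 9 and 12 DPA. Each of the 12 groups had 3 biological replicates, for 36 libraries. Gene counts per library ran from 137649 to 3539295 with a median of 912926. Between 13605 and 20589 genes were detected per library, and 11595 of the 36573 genes had no count in any library. Depth differed between groups, from a mean of 223630 gene counts in 2C nuclei at 6 DPA to 1926720 in 32C nuclei at 9 DPA. The most abundant gene took 0.702% of the counts in any library, and the 100 most abundant genes together took 9.64 to 13.4%.

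The libraries were ordered by DNA content and by stage. Principal component 1 held 21.5% of the variance and ran from a mean of -89.0 in 2C nuclei at 6 DPA to 64.6 in 32C nuclei at 12 DPA. Within each stage its group means rose with every doubling of DNA content. Component 2 held 12.4% and separated 6 DPA, with group means of -51.5 to -30.9, from 12 DPA, with group means of 7.96 to 61.2. At 9 DPA the 4C nuclei lay at 49.4 ± 15.9 (SD, n = 3) and the 32C nuclei at -17.1 ± 4.23 on this component.

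**Figure D1:**
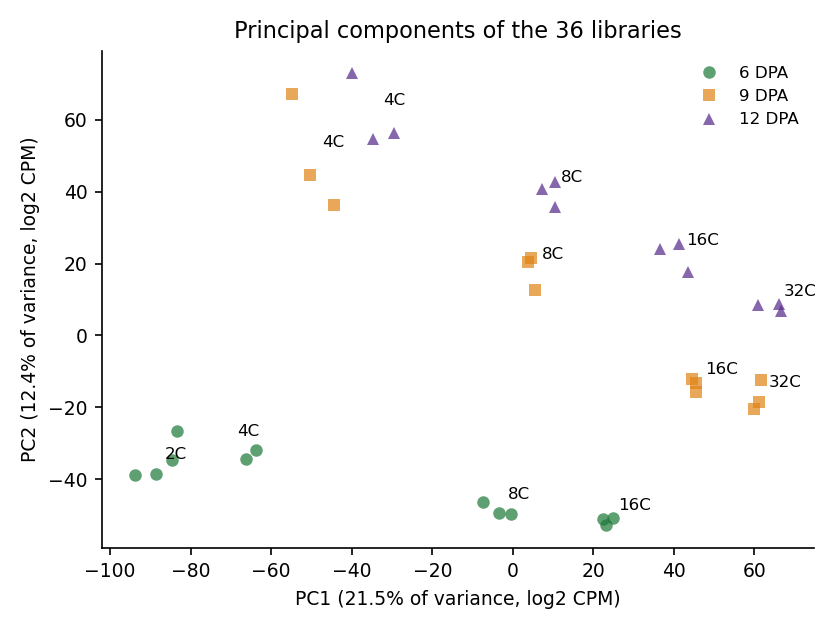
Each point is 1 of the 36 libraries, placed by its first and second principal components of log2 CPM; shape and colour give the stage, and the label beside each group gives the DNA content. Libraries of higher DNA content lie further right within each stage, and the 6 DPA libraries lie lowest.

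The amount of RNA per nucleus rose with DNA content at every stage. At 6 DPA, gene counts per ERCC count went from 144 ± 19.6 (SD, n = 3) in 2C nuclei through 401 ± 230 in 4C and 1245 ± 195 in 8C to 2216 ± 273 in 16C nuclei. At 9 DPA the ratio went from 95.6 ± 32.0 in 4C nuclei through 144 ± 54.9 and 593 ± 163 to 1308 ± 537 in 32C nuclei. At 12 DPA it went from 252 ± 108 in 4C nuclei through 591 ± 282 and 1776 ± 576 to 4347 ± 1556 in 32C nuclei. As fitted over the whole range, the ratio rose per doubling of DNA by 2.58-fold at 6 DPA, 2.51-fold at 9 DPA and 2.66-fold at 12 DPA. Single steps differed. From 4C to 8C at 9 DPA the log2 ratio rose by 0.592 ± 0.433 (SE), or 1.507-fold. From 8C to 16C at 6 DPA it rose by 0.836 ± 0.164, or 1.785-fold. Both lay below the rise of DNA itself, and every other step lay above it, up to 4.18-fold from 8C to 16C at 9 DPA.

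The slopes on the log2 scale were 1.37 (permutation p = 2e-05, adjusted p = 3e-05), 1.33 (p = 1e-04, adjusted p = 1e-04) and 1.41 (p = 2e-05, adjusted p = 3e-05) over 12 libraries each. Fitted within each replicate number, they were 1.37 ± 0.102 at 6 DPA, 1.33 ± 0.0866 at 9 DPA and 1.41 ± 0.310 at 12 DPA (SD, n = 3). RNA in proportion to DNA would give a slope of 1. Against that value the two-sided permutation p was 0.025 at 6 DPA, 0.0646 at 9 DPA and 0.0208 at 12 DPA, with adjusted p of 0.0375, 0.0646 and 0.0375, so the difference from proportion was larger than chance at 6 and 12 DPA and did not pass at 9 DPA. All 9 slopes of single replicate numbers lay above 1, from 1.11 to 1.73 (two-sided exact sign-flip p = 0.00391). The ratio rests on 142 to 13452 ERCC counts per library and on equal numbers of sorted nuclei.

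**Figure D2:**
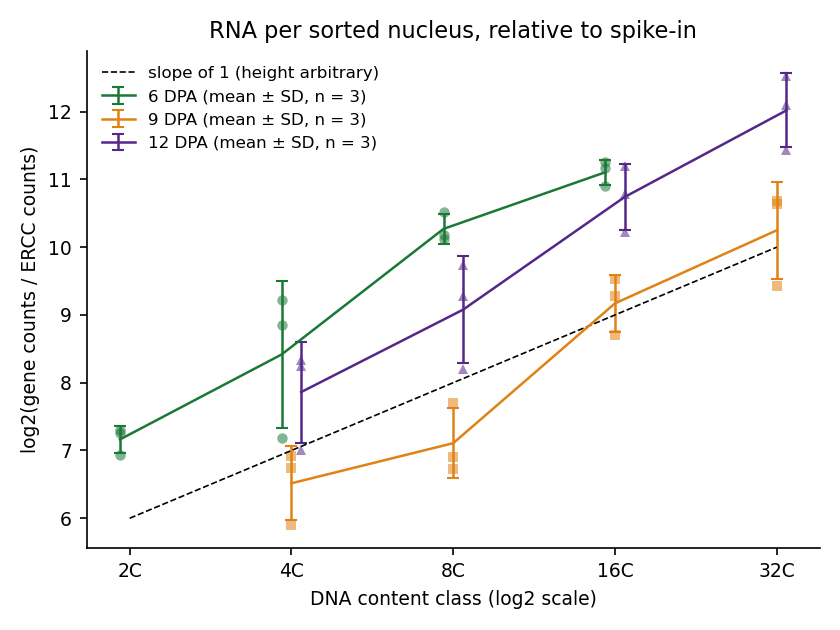
The vertical axis is the log2 ratio of gene counts to ERCC counts and the horizontal axis the DNA content class on a log2 scale; points are libraries, and lines join group means with SD bars (n = 3). The 3 stages rise with slopes of 1.37, 1.33 and 1.41, steeper than the dashed line, which has a slope of 1 and an arbitrary height.

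At equal DNA content, RNA per nucleus was lowest at 9 DPA. Averaged over 4C, 8C and 16C nuclei, the log2 ratio fell by 2.33 from 6 to 9 DPA, which left 0.199 of the earlier ratio, and rose by 1.63 from 9 to 12 DPA, a 3.09-fold rise. Both differences had the same sign in all 3 classes (exact permutation p = 0.00025, adjusted p = 0.000375 for each, two-sided). From 6 to 12 DPA it fell by 0.70 (exact permutation p = 0.0415, adjusted p = 0.0415). Nuclei of different stages came from separate preparations, with more fruits at 6 DPA than at the later stages, so stage and preparation cannot be told apart here.

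Many genes changed their share of the nuclear RNA with DNA content at 6 DPA. The slope was called for 3201 of 13545 genes tested, of which 1524 rose and 1677 fell as DNA content increased. Between the ends of the range, 1420 genes were higher in 16C than in 2C nuclei and 1482 were lower. The genes that were higher in 16C nuclei differed by a median of 2.44-fold, and those that were lower by a median of 3.59-fold. With the 57 called genes that had no count in one of these classes set at the limit that 3 counts per library allow, the medians were 2.40 and 3.38-fold.

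At 9 DPA fewer genes were called, with a slope for 1470 of 11992 genes tested. Of these, 636 rose and 834 fell with DNA content. In 32C nuclei, 722 genes were higher and 794 lower than in 4C nuclei, by medians of 2.83 and 4.87-fold (2.78 and 4.54-fold with 27 genes at their limit). With the DESeq2 test 688 slopes rose and 1347 fell, and with a filter on a mean of 1 CPM 782 rose and 1300 fell, over 18775 and 18398 genes tested. With the spread estimated over all 36 libraries, 2985 slopes and 2727 differences between 32C and 4C were called over 16481 genes tested. The number of calls is not a measure of the difference between stages, since depth and the number of genes tested differed.

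At 12 DPA the slope was called for 2849 of 14863 genes tested, with 1293 rising and 1556 falling. Between 32C and 4C nuclei, 1380 genes were higher and 1583 lower. Their medians were 2.23-fold and 3.43-fold (2.22 and 3.42-fold with 67 genes at their limit). At all 3 stages the genes that fell moved further than those that rose. These counts are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The slope and the comparison of the end classes use the same libraries and are not independent of each other. With all libraries of a stage thinned to the depth of the shallowest, the slope was called for a median of 1507 genes at 6 DPA, 721 at 9 DPA and 1262 at 12 DPA, out of 6413, 5141 and 7929 genes tested.

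**Figure D3:**
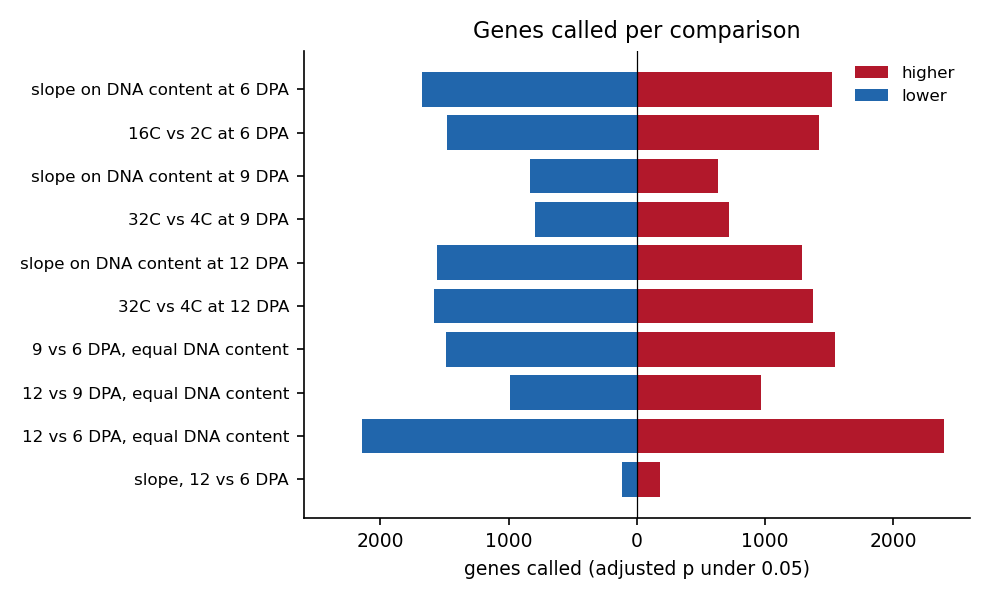
Bars give the number of genes called higher (right) and lower (left) in each comparison at an adjusted p under 0.05; for slopes, higher means a rise with DNA content. The slope at 6 DPA has 1524 genes to the right and 1677 to the left, and the bar for 12 versus 6 DPA is the longest.

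Genes called at more than 1 stage nearly always changed in the same direction. Of 11560 genes tested at all 3 stages, 391 rose and 429 fell with DNA content at each of them, against 7.70 and 7.67 expected from independent lists. Some of the falling genes carried neighbouring identifiers and had similar slopes, so these numbers need not count separate changes. Only 31 genes were called with opposite directions at any pair of stages. Across genes, which are not independent replicates, the slopes correlated with r = 0.719 (rho = 0.536) between 6 and 9 DPA, 0.725 (0.586) between 6 and 12 DPA and 0.834 (0.622) between 9 and 12 DPA. The fits of the 3 stages share no library. The total of 820 shared genes was 376 without replicate 2 and 516 without replicate 1 of every group.

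**Figure D4:**
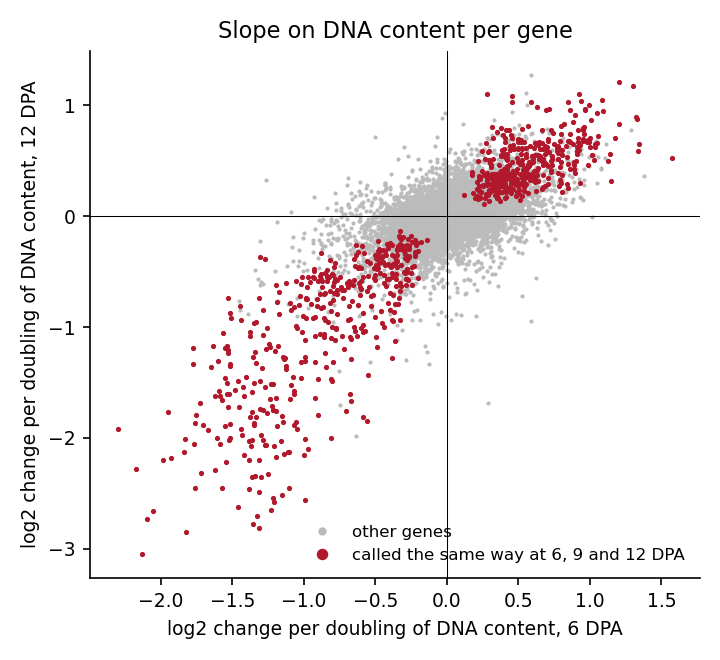
Each point is 1 of 11560 genes, with the log2 change per doubling of DNA content at 6 DPA on the horizontal axis and at 12 DPA on the vertical axis; red points are the genes called in the same direction at 6, 9 and 12 DPA. The 429 shared falling genes spread over steeper slopes than the 391 shared rising genes.

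The identifiers with the largest shared slopes illustrate the range; the table does not pair them with gene names. Sly11g0297801 rose from 106 ± 35.5 CPM (SD, n = 3) in 2C to 943 ± 278 CPM in 16C nuclei at 6 DPA, and from 182 ± 84.3 CPM in 4C to 2002 ± 296 CPM in 32C nuclei at 12 DPA. Sly07g0109061 rose from 15.7 ± 4.58 to 161 ± 17.8 CPM at 6 DPA and from 34.3 ± 20.1 to 401 ± 146 CPM at 12 DPA between the same classes. Their edgeR slopes at 12 DPA were 1.21 ± 0.0627 (SE, adjusted p = 4.21e-13) and 1.18 ± 0.126 (adjusted p = 1.88e-07) per doubling. Sly09g0081321 fell from 155 ± 27.9 CPM in 2C to 2.73 ± 2.63 CPM (2 to 3 counts per library) in 16C nuclei at 6 DPA, and from 168 ± 69.9 CPM in 4C to 2.70 ± 0.719 CPM (3 to 5 counts) in 16C nuclei at 12 DPA. At 9 DPA it had 98.3 ± 30.1 CPM in 4C nuclei and no count in any 32C library, where 3 counts per library would be 0.848 to 6.86 CPM, so it was at least 14.3-fold lower. Sly06g0382211 had 153 ± 28.2 CPM in 4C and 22.7 ± 7.27 CPM in 8C nuclei at 12 DPA, with a slope of -2.45 ± 0.167 (SE, edgeR adjusted p = 7.41e-11). At 6 DPA it was higher in 4C (48.3 ± 14.4 CPM) than in 2C nuclei (15.3 ± 9.86 CPM, 1 to 5 counts), and its slope per nucleus was not called there (edgeR adjusted p = 0.137).

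Counted per nucleus rather than as a share, nearly all genes rose with DNA content. Scaled to ERCC counts, 12967 of 13545 genes rose at 6 DPA, 11618 of 11992 at 9 DPA and 14287 of 14863 at 12 DPA. Of the estimates, 85.6, 90.1 and 91.2% lay above 1. Of the genes whose share fell, only 27 of 1677 at 6 DPA, 125 of 834 at 9 DPA and 139 of 1556 at 12 DPA also fell per nucleus. For 529, 231 and 403 of them no change per nucleus was called, and the others rose. With a filter on a mean of 1 CPM, 67, 304 and 197 genes fell per nucleus. These calls rest on edgeR's quasi-likelihood test and share the error of each library's ERCC total across all genes, so they are not independent of one another or of the ratio of totals.

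Between stages at equal DNA content, most calls were made across the longest interval. From 6 to 12 DPA, 2396 genes rose and 2143 fell among 16024 tested, by medians of 1.79-fold and 2.03-fold (each lower by 0.01 with 18 genes at their limit). From 6 to 9 DPA, 1548 rose and 1490 fell, by medians of 1.64 and 2.07-fold (1.64 and 2.06-fold with 15 at their limit). From 9 to 12 DPA, 969 rose and 988 fell, by medians of 1.96 and 1.68-fold in either case for the 2 genes at their limit. The comparisons share libraries, and as above each stage was a separate preparation.

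The relation to DNA content itself was also compared between 12 and 6 DPA. Over 4C, 8C and 16C nuclei, 290 of 15538 genes tested had different slopes, of which 179 were higher and 111 lower at 12 DPA. Among the 179, the estimated slope was negative for 165 at 6 DPA and for 67 at 12 DPA. Among the 111, it was negative for 28 at 6 DPA and for 102 at 12 DPA. The test is edgeR's interaction term with Benjamini-Hochberg adjustment, which recovered 52.7% of simulated slope differences of 1 and 8.14% of those of 0.5, so the count does not show how few genes differed. The count was 181 without replicate 3 of 4C nuclei at 6 DPA and 190 without replicate 2 of 4C nuclei at 12 DPA.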

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

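The ERCC tests below were chosen after the result was seen, as were the tests at equal depth; the difference between slopes was planned.

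The slope on DNA content differed between 12 and 6 DPA for 290 genes, a tested difference between the stages. Of the 179 genes with a higher slope at 12 DPA, 136 were called falling with DNA content at 6 DPA and 31 at 12 DPA, while 46 were called rising at 12 DPA. Of the 111 with a lower slope, 41 were called rising at 6 DPA and 74 falling at 12 DPA. Of 100 splits that reassigned stage within each class, 2 gave as many genes, the real one included, and the other one gave 2539. That split kept the 12 DPA label on 3 of 3 libraries of 4C, 1 of 8C and 0 of 16C, so it turned the difference between stages into a difference of slopes, a structure of these samples rather than a slope effect. The splits do not keep the difference between stages, so they cannot tell whether chance gave the 290. The count was 181 without replicate 3 of 4C nuclei at 6 DPA and 190 without replicate 2 of 4C nuclei at 12 DPA.

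Libraries of higher DNA content were mostly deeper, which could by itself give slopes. With the libraries of a stage thinned to equal depth, slopes correlated across genes with those at full depth at r = 0.961 or more. Of the genes called at full depth and still tested, 99.89 to 100% kept their direction. Fewer genes could be tested, and of those still tested fewer were called. Of the called genes, 2070 to 2082 of 3201 were still tested at 6 DPA and 943 to 963 of 1470 at 9 DPA. At 12 DPA it was 1857 to 1903 of 2849. For these genes the values argue against unequal numbers of reads as the source of the slopes. The other called genes were not checked. Thinning keeps the same libraries, so it cannot test what differed before sequencing. The amount of RNA per sample, which rose with DNA content, is one such difference. Splits of the libraries gave no comparable count: in 100 splits each, the real one was the only 1 with as many genes, with 3201 genes at 6 DPA against 0 in the highest other, 1470 at 9 DPA against 4 and 2849 at 12 DPA against 839. For the 820 shared genes the highest other was also 0. No other split at 6 DPA called any gene, so none could be shared, and this adds nothing for the shared genes. For the end classes, 10 splits are too few for a share under 0.05; the real counts were 2902, 1516 and 2963, and the highest other was 0 in each case. What differs between nuclei of these classes besides DNA content, such as tissue layer, cell type or whether the cell was dividing, was not tested.

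As fitted over the range of classes, RNA per nucleus rose faster than DNA content, with a mean of 1.37 over the 9 slopes of single replicate numbers. It did not do so at every single step, and the test against proportion did not pass at 9 DPA alone. Stronger nuclease depletion of the abundant ERCC species in libraries with much RNA was tested on the log2 ratio of the 5 most abundant species to the others, which changed by 0.106 ± 0.0394 (SE, n = 12, permutation p = 0.0204), -0.022 ± 0.020 (p = 0.296) and -0.0866 ± 0.0374 (p = 0.0334) per doubling at 6, 9 and 12 DPA. As the whole cause it would need values below -0.368, -0.326 and -0.414, which argues against it. With only the other species as reference, the slopes of RNA per nucleus were 1.455, 1.309 and 1.343. A part at 12 DPA, and a depletion shared by all species, stay open. A difference between classes in the number of nuclei sorted or in RNA recovery cannot be told apart from a true rise, because either would enter the same ratio. For the slopes per nucleus, 100 splits each gave 1 with as many genes, the real one, with 12994 genes against 0 in the highest other at 6 DPA, 11743 against 10458 at 9 DPA and 14426 against 13897 at 12 DPA. The highest others at 9 and 12 DPA came near the real counts, and what these splits had in common was not tested.

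Between stages, 100 splits each gave 1 with as many genes, the real one. The real counts and the highest others were 3038 and 143 for 9 versus 6 DPA, 1957 and 22 for 12 versus 9 DPA, and 4539 and 512 for 12 versus 6 DPA.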

How the results depend on the processing

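Chosen after seeing the data were the equal-depth fits, the fits without 3 shallow libraries of 4C and 8C, and all tests of neighbouring classes and of curvature; the rest were planned. A few called slopes changed sign at equal depth. Near-even balances of rises and falls turned. With DESeq2 size factors they went from 1548 and 1490 to 1424 and 1600 (9 versus 6 DPA) and from 2396 and 2143 to 2247 and 2289 (12 versus 6 DPA). Without a filter, that of 16C versus 2C at 6 DPA went from 1420 and 1482 to 1666 and 1581. Those for 12 versus 9 DPA and the slope at 6 DPA turned under other alternatives. The cause was not tested. Where DESeq2 size factors, the DESeq2 test or the 1 CPM filter were run on planned results, totals of called genes stayed within 1.5 times their value; neither DESeq2 alternative was run per nucleus, nor the size factors for shared genes. The directions moved more: at 9 DPA 834 falling slopes became 1347 with the DESeq2 test and 1300 with the 1 CPM filter, and with that filter 67 and 304 genes fell per nucleus at 6 and 9 DPA, against 27 and 125; the cause was not tested. No gene exceeded 1% of a library, so that removal changed nothing. The gene list tests were not run, for want of names. At equal depth the slope counts were 1507, 721 and 1262 at 6, 9 and 12 DPA, with fewer genes tested. Without a filter, slopes at 9 DPA numbered 2502 and slope differences 477, with more genes tested. In 1 fit of all 36 libraries, 2985 slopes and 2727 differences between 32C and 4C were called at 9 DPA; the cause was not tested. Shared genes numbered 509 at an adjusted p under 0.01, a stricter threshold. Without the shallow libraries, slopes numbered 3528 at 6 DPA and 1515 at 9 DPA, and slope differences 268.

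Leaving out single libraries gave 2579 to 3528 slopes at 6 DPA, 1122 to 1665 at 9 DPA and 2220 to 3257 at 12 DPA. It gave 2250 to 3365, 1189 to 1722 and 2272 to 3392 differences between the end classes, 2449 to 3125, 1692 to 2089 and 4004 to 4834 between stages (9 versus 6, 12 versus 9 and 12 versus 6 DPA), and 181 to 336 slope differences. Per nucleus the counts were 11923 to 14618, 12328 to 12562 and 14414 to 15280, and the slopes of the ratio 1.27 to 1.49 over the 3 stages. Shared genes numbered 376 to 674 without a replicate number; fewer libraries were then fitted, and the cause was not further tested.

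Samples were not paired by replicate number, since not all such pairs correlated over 0.1. At 6, 9 and 12 DPA, 0, 1 and 13 of 18 did. Deviations correlated at means of 0.0438, 0.0396 and 0.134, against -0.022, -0.019 and -0.0668 for other pairs. Equal numbers were more alike, and 12, 11 and 12 of 12 libraries correlated best with their own number. The main fits leave this likeness out. With that number as a block, slopes numbered 3073, 1473 and 3284, end-class differences 3011, 1554 and 3755, stage differences 3377, 2384 and 4878, slope differences 387, shared genes 868, and genes called per nucleus 13048, 11755 and 14526. Counts between neighbouring classes rose to 476 and 567 (8C to 16C and 16C to 32C at 12 DPA, with 152 and 124 rising) and 66 (16C to 32C at 9 DPA), and curvature to 138 at 9 DPA and 637 at 12 DPA. Of 1673 calls at the 5 upper steps 77.6% then fell and 375 rose, against 88.6% and 119 without the block, and of 3788 at the lower ones 50.7%. Permutation within replicate numbers, which leaves the slopes of the ratio at 1.37, 1.33 and 1.41 by construction, gave p = 0.00011, 0.00025 and 0.00011. The calls miss many small changes: slopes of 0.5 were recovered for 56.6% of simulated genes that passed the filter at 6 DPA and slope differences of that size for 8.14%. The simulation did not vary depth, so it does not tell how far depth sets this limit.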

Other observations

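All tests in this part were chosen after the main results were seen. From one class to the next, the direction of changes in share depended on where in the range the step lay. At the 4 steps that start at 2C or 4C, 3114 calls were made, of which 52.8% fell. At the 5 steps that start at 8C or above, 1048 calls were made, of which 88.6% fell. For example, from 8C to 16C at 6 DPA, 12 genes rose and 254 fell, and from 16C to 32C at 12 DPA, 17 rose and 262 fell. With the replicate number as a block, these were 28 and 278, and 124 and 443. The pooled share that fell was then 77.6% of 1673 calls at the upper steps and 50.7% of 3788 at the lower ones. Leaving out any library of a step, without the block, kept that share between 87.5 and 90.8% at the upper steps and between 50.7 and 53.6% at the lower ones. Of the 254 genes, 219 could be tested from 8C to 16C at 12 DPA, in other libraries, and 91.3% of their estimates were negative there, against 50.3% over all genes.

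Scaling and depth were tested as causes of the falls in share at the upper steps, and the tables argue against both. With DESeq2 size factors 88.6% of the calls fell, with library sizes alone, which assume nothing of most genes, 89.0%, and at equal depth 80.6 to 86.7% over the 5 draws, although only 269 calls a draw were then made. None of these fits used the replicate block. Carry-over of 4C nuclei into the 8C gate could not enter the steps from 16C to 32C, which do not compare 8C nuclei. There, 39 of 39 calls at 9 DPA and 262 of 279 at 12 DPA fell. For the steps from 8C to 16C carry-over cannot be told apart. Of 219 genes, 26% were higher in 8C than in 4C at 12 DPA (95% exact binomial interval 20.3 to 32.4%). The interval treats genes as independent, which they are not, so it does not measure the spread between libraries. By that interval the share neither clears the bound set against carry-over nor lies as low as carry-over would need. Of these genes, 16 were called higher and 80 lower in 8C. A biological difference between the classes stays open and untested. Steps were not tested per nucleus. At equal depth, 0 to 2 genes were called from 16C to 32C at 9 DPA over the 5 draws.

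For each step there are 10 splits, too few for a share under 0.05, and the real one was the only 1 of them with as many genes. The real count and the highest other were 326 and 7 from 2C to 4C, 1542 and 0 from 4C to 8C and 266 and 5 from 8C to 16C at 6 DPA. At 9 DPA they were 407 and 1 from 4C to 8C, 230 and 1 from 8C to 16C and 39 and 16 from 16C to 32C. At 12 DPA they were 839 and 0, 234 and 0, and 279 and 4. Several counts depend on single libraries. At 6 DPA, the step from 2C to 4C gave 211 and 197 without replicates 1 and 3 of 2C and 213 without replicate 3 of 4C, and the step from 8C to 16C gave 176 without replicate 2 of 8C and 159 and 128 without replicates 1 and 2 of 16C. At 9 DPA, 4C to 8C gave 239 without replicate 2 of 4C, 8C to 16C gave 150 without replicate 1 of 16C, and 16C to 32C gave 24 and 20 without replicate 2 of 16C and of 32C, and 81 (76 of them fell) with a filter on a mean of 1 CPM. At 12 DPA, 4C to 8C gave 501 without replicate 3 of 4C, and 8C to 16C gave 141 without replicate 3 of 16C.

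Some genes curved over the 4 classes instead of changing evenly. The curvature was called for 213 genes at 6 DPA, 91 at 9 DPA and 321 at 12 DPA, of which 210, 70 and 270 bent downward, with the middle classes above a straight line. In 100 splits each, 2 gave as many genes at 6 DPA (highest other 340), 6 at 9 DPA (highest other 355) and 2 at 12 DPA (highest other 475), the real one included. The splits exchange classes and so do not keep the slope on DNA content, and they cannot tell whether chance gave the curvature. The highest other at 9 DPA, several times the real count, points to a structure of the samples. Over the 99 other splits, the number of genes rose with the absolute correlation of the curvature term with the real DNA content at rho = 0.340, 0.479 and 0.170 for 6, 9 and 12 DPA. That correlation was 0.596, 0.745 and 0.596 in the splits with the most genes, and up to 0.745 in others at 6 and 12 DPA. The counts fell to 141 and 127 without replicates 1 and 3 of 2C and 132 without replicate 3 of 4C at 6 DPA, and to 54 without replicate 2 of 4C at 9 DPA, where a filter on a mean of 1 CPM gave 144. With the replicate number as a block they were 189 at 6 DPA, 138 at 9 DPA and 637 at 12 DPA.

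Genes lower at high DNA content were more often higher at 12 than at 6 DPA. Of genes called on the slope at 9 DPA and between 12 and 6 DPA, whose contrasts share no library, 331 fell with DNA content and rose with stage, against 135 expected from independent lists, and 194 rose with DNA content and fell with stage, against 88.2. The other combinations were also above their expected numbers, 155 against 103 for a rise in both and 151 against 116 for a fall in both. Across genes, r was -0.198 and rho -0.108. A hypothesis was that the lowest classes became more unlike the higher ones with stage. It was not borne out: genes that fell with DNA content changed from 6 to 12 DPA by a median of 0.194 (log2) in 4C, 0.342 in 8C and 0.200 in 16C nuclei, a difference of -0.006 between 4C and 16C. Measured on mean log2 CPM, that difference was 0.0459, and -0.0123 to 0.0829 when single libraries were left out.

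At equal depth, fewer genes were detected at the highest DNA content at 6 and 12 DPA. With every library thinned to 137649 counts, 15208 ± 256 genes (SD, n = 3) were detected in 2C and 14655 ± 93.7 in 16C nuclei at 6 DPA, and 15225 ± 131 in 4C and 14409 ± 75.0 in 32C nuclei at 12 DPA. At 9 DPA the 32C mean was also the lowest, but the classes differed by less than its SD. The values were 13995 ± 388 in 4C, 14110 ± 424 in 8C, 14187 ± 162 in 16C and 13931 ± 480 in 32C nuclei. These differences were not tested. At full depth, the share of the 100 most abundant genes rose by 0.426 points per doubling at 12 DPA (permutation p = 0.00339, adjusted p = 0.0102) and did not pass at 6 DPA (0.211 points, adjusted p = 0.132) or 9 DPA (0.179 points, adjusted p = 0.395). This share was not computed at equal depth.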
